A study of Mus musculus with 10 samples.

How the data were processed

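The samples were full-thickness back skin of male C57BL/6 mice aged 7 to 8 weeks. The hair of the back had been removed with wax, which starts a new growth phase of the hair follicles (anagen), and cyclophosphamide, a prodrug whose products alkylate and crosslink DNA, was injected intraperitoneally at 150 mg/kg on day 9 after depilation. RNA was sequenced from skin taken before the injection (0h) and 6h, 12h, 24h and 48h after it, with 2 libraries per time and 10 in all. The samples used here include no mice injected with vehicle, so time since injection and time since depilation pass together. The time of day at which skin was taken is not given in the labels, so its part in a change cannot be told apart. The labels do not state whether the 2 libraries of a time came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

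The values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) in the gene table the authors deposited. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse build mm10 were used. The notes give no role or order of the tools, and the gene annotation, filters and any scaling between libraries are not given in the sources used here. The unit was read from the use of Cufflinks and from values that are not whole numbers and sum to different totals, since the table's header names none. The table had 24358 rows and 10 columns of values, all of which were used. In 27 rows the gene symbol had been turned into a date, and these rows were left out, which left 24331 genes. 103 rows name several genes that were counted together. The columns carry the replicate numbers 2 and 3, while the labels number the libraries 1 and 2, so each column was matched to its time only, and libraries are called here by the number in the table.

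The FPKM of a library summed to between 863187 and 979067. Absolute depth is not known from FPKM. The most frequent ratios between low values (up to 0.1 FPKM) of 2 libraries gave their relative depth, from 1 in 0h library 2 to 1.46 in 0h library 3, with the other libraries between 1.02 and 1.22. Correlations of log2(FPKM + 1) over the tested genes were between 0.984 and 0.989 for the 2 libraries of a time and between 0.966 and 0.987 for libraries of different times, and no pair of libraries held identical values.

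Changes were tested with limma 3.58.1 (R 4.3.3; linear model with 1 mean per time, empirical Bayes moderation with an intensity trend) on log2(FPKM + 1). All 10 libraries entered 1 fit, so that the times shared 1 estimate of the spread, with 5 residual degrees of freedom and a median prior of 4.92. Genes with at least 1 FPKM in at least 2 libraries were tested (13625 genes), and an adjusted p (Benjamini-Hochberg over genes, two-sided) under 0.05 was the threshold. A fold change is a difference on the log2(FPKM + 1) scale and understates the change of low genes. Each later time was compared with 0h, and 12h with 6h, 24h with 12h, 48h with 24h and 48h with 6h. An F test over the 4 comparisons with 0h found genes that changed at any time. Errors of FPKM are SD over n = 2 libraries, and errors of fold changes are the standard error (SE) of the fit, unless stated otherwise.

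Gene lists for p53 targets, cell division, DNA repair, hair follicle compartments and pathways, the other cell types of skin, and stress, immune and clock genes were fixed before the data were examined, as were the comparisons, the test, the rule for named genes and all alternatives except fry. Lists were tested against all other genes with camera (limma; preset correlation 0.01), adjusted over 132 tests of 33 lists at 4 times. Camera with an estimated correlation was an alternative, and so was fry, a rotation test of whether the genes of a list move on balance 1 way. A list of genes encoded by the mitochondrial genome was not analysed here. Of the 132 tests 71 passed the threshold with the preset correlation, 0 with the estimated correlation (adjusted p from 0.413 to 0.757 for those 71) and 1 with fry. The median, the mean and the test of a list had the same sign in all 71. Counts of list members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

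The genes named in the text are, per comparison with 0h, the 10 largest rises and 10 largest falls past the threshold with at least 5 FPKM in the higher group and both libraries on the same side of both 0h libraries, leaving out predicted genes and clones. Up to 4 members past the threshold with the largest change are named from each list, and Cdkn1a, Mdm2, Trp53, Bax, Mki67, Shh, Lef1, Wnt10b, Krt35, Dct, Per2 and Adipoq whatever their values. Between later times the rule took the 3 largest rises and falls. Some genes that met the rule are withheld and left out of the text. Genes named outside this rule were chosen after their values were seen and are marked so, except for receptor, atrophy and myogenic genes of muscle. How those were chosen is given where they are named. Of 173 named genes 166 matched 1 gene each of the GENCODE M21 annotation of GRCm38, the assembly also called mm10, from which coordinates (counted from 1) were taken. Members of multigene families, such as keratin-associated proteins and haemoglobins, can share reads, and their single values are uncertain.

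The test was checked on simulated data made from the 13625 tested genes, for 48h against 0h. It called 94% of genes changed by 1 on the log2 scale and 100% of genes changed by 2, and 3.5% of its calls were unchanged genes. With nothing changed it called 1 gene. The list test found 100% of lists shifted by 0.5 and called 4% of unshifted lists. The genes were simulated independently of each other, so this cannot show how the list test behaves when genes of a list vary together. Noise was normal, with the spread of each gene taken from the fit itself and nothing shared within a library. The rates for single genes therefore hold for data that meet the model and may be too favourable for these libraries. Changed genes were drawn only from those with a mean log2(FPKM + 1) above that of 5 FPKM, so the check does not cover lower genes. The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, 3 other scalings (median of ratios, quantile normalization, and hair shaft keratins with keratin-associated proteins left out and the rest rescaled), a fit of only the 2 times compared, limma without trend, the replicate number as a block, and leaving out each library in turn. A fold change does not move when the library left out belongs to neither time compared. Genes called in the full fit were picked for differing in these same libraries, so a kept sign is weak evidence of stability. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.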

Results

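The transcriptome of growing-hair skin was followed from before a single dose of cyclophosphamide to 48h after it, with 2 libraries at each of 5 times. The most abundant transcripts encode proteins of the hair shaft. Krtap8-1 or Krtap22-2, both keratin-associated proteins, had the highest FPKM in every library. Hair shaft keratins and keratin-associated proteins together held 12.4% ± 1.58 (SD, n = 2) of the summed FPKM at 0h, 13.4% ± 0.113 at 6h, 16.9% ± 0.453 at 12h, 17.1% ± 2.18 at 24h and 16.7% ± 1.47 at 48h. The first principal component held 30.5% of the variance and the next 17.2%. Of 13625 genes tested, 1002 changed at any time after the injection (limma F test). The number past the threshold against 0h was 6 at 6h, 147 at 12h, 452 at 24h and 1215 at 48h.

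**Figure D1:**
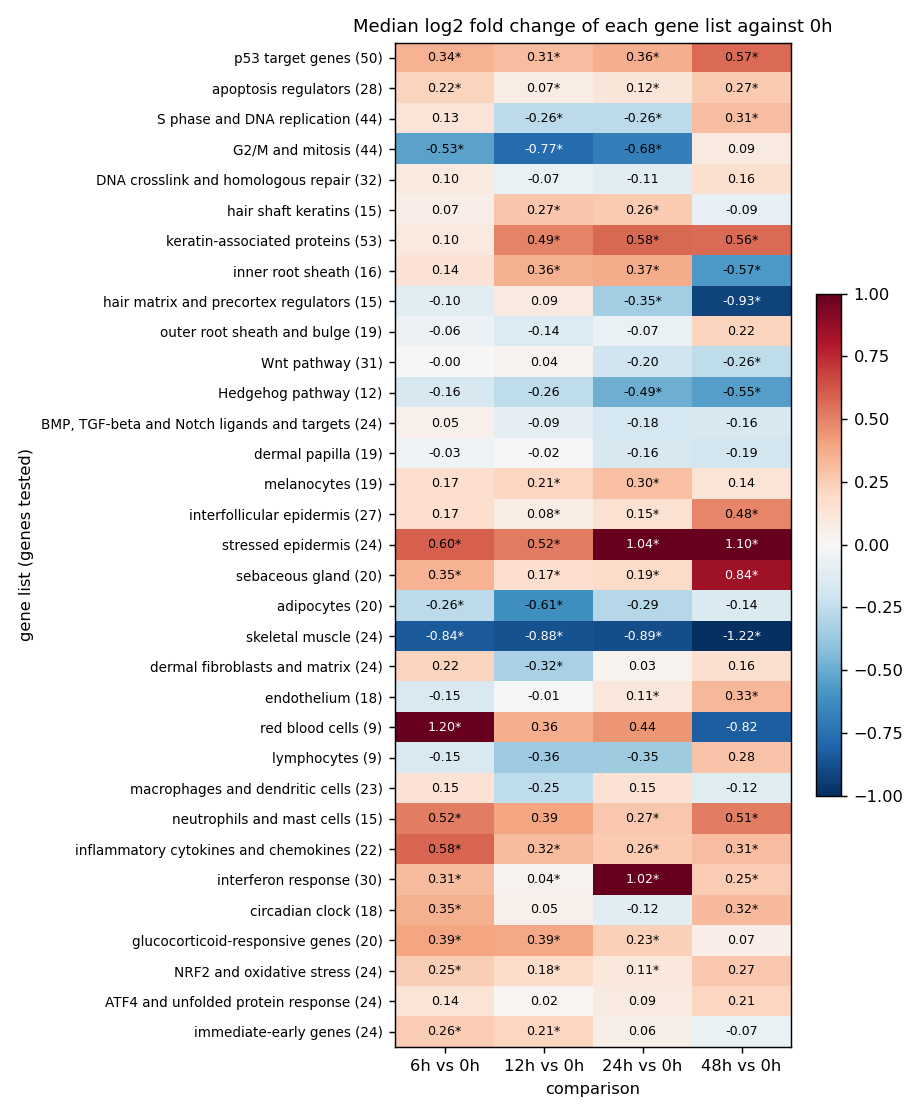
Median log2 fold change against 0h (log2(FPKM + 1) scale) of each gene list fixed before the data were examined, with lists in rows, the number of genes tested in brackets and times in columns. An asterisk marks an adjusted p under 0.05 with the preset correlation, and 0 of the 71 marked tests passed with an estimated correlation. The G2/M list lies at -0.77 at 12h and 0.09 at 48h, and the interferon list at 1.02 at 24h.

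The comparison of 6h with 0h asks what changed first after the drug. Il1b, which encodes the inflammatory cytokine interleukin 1 beta, rose from 0.704 ± 0.147 FPKM (SD, n = 2) at 0h to 5.81 ± 0.0567 at 6h (log2 fold change 2.0, SE 0.15, adjusted p = 0.00209). Lbp, which encodes a secreted protein that binds bacterial lipopolysaccharide, rose from 7.71 ± 0.446 to 26.7 ± 4.53 FPKM (log2 fold change 1.66, SE 0.19, adjusted p = 0.0239). Lmod2, an actin filament nucleator of muscle, rose from 8.25 ± 0.926 to 20.1 ± 1.83 FPKM (log2 fold change 1.19, SE 0.13, adjusted p = 0.0239). The other rise was of Has1, a hyaluronan synthase, and the 2 falls were of Ank1 and Gm15816. These 3 genes fell outside the rule for named genes. The 6 calls were 4 genes higher and 2 lower, with 1671 genes at an unadjusted p under 0.05. The split was 8 and 0 without 6h library 2, where 3 of the 6 calls were kept, and 1 and 5 without 6h library 3, where 1 was kept.

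Single genes at 6h were mostly short of the threshold, while several whole lists lay apart from other genes with the preset correlation. Of 50 p53 target genes, which the DNA damage regulator p53 activates, 0 passed over all genes and 23 were higher adjusted over the list alone, with a median log2 fold change of 0.34 (adjusted p = 7.77e-12, and adjusted p = 0.413 with an estimated correlation). Mdm2, the ubiquitin ligase that limits p53, was at 20.9 ± 1.64 against 14.2 ± 0.997 FPKM (adjusted p = 0.147), and Cdkn1a, the p21 inhibitor of cell division, was at 273 ± 22.7 against 190.4 ± 0.825 FPKM (adjusted p = 0.15). Of 44 G2/M and mitosis genes, 0 passed over all genes and 10 were lower adjusted over the list alone, with a median of -0.53 (adjusted p = 9.44e-18, and adjusted p = 0.507 with an estimated correlation). Of 22 inflammatory cytokines and chemokines, 1 rose and 9 were higher adjusted over the list alone (median 0.58, adjusted p = 1.63e-10, and adjusted p = 0.413 with an estimated correlation). Of 24 skeletal muscle genes, 0 passed over all genes and 19 were lower adjusted over the list alone (median -0.84, adjusted p = 7.33e-18, and adjusted p = 0.413 with an estimated correlation). Red blood cell genes had a median of 1.20 (9 genes, 0 past the threshold, adjusted p = 0.00549, and adjusted p = 0.507 with an estimated correlation), and the haemoglobin row Hbb-b1,Hbb-bs ranged from 0.598 FPKM in 48h library 3 to 746 FPKM in 6h library 2. The median of all genes was 0.04 at 6h. The count of 6 was 2 without 0h library 2, 1 without either 48h library, and 14 without either 12h or either 24h library. It was 35 in a fit of the 2 times alone, 3 with no filter on low values and 2 with a mean of at least 5 FPKM. Il1b passed with each library left out.

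By 12h single p53 targets and genes of dividing cells passed the threshold. Bbc3, which encodes the pro-apoptotic p53 target PUMA, rose from 8.55 ± 0.199 to 23.6 ± 1.05 FPKM (log2 fold change 1.37, SE 0.24, adjusted p = 0.0345). Dcxr, a carbonyl reductase, rose from 35.4 ± 0.522 to 72.6 ± 3.70 FPKM (log2 fold change 1.01, SE 0.12, adjusted p = 0.0137). Cks2, a subunit of cyclin-dependent kinases, fell from 104 ± 3.97 to 40.4 ± 7.44 FPKM (log2 fold change -1.36, SE 0.19, adjusted p = 0.0155). Casq1, the calcium store protein of fast muscle fibres, fell from 236 ± 0.742 to 80.4 ± 28.4 FPKM (log2 fold change -1.59, SE 0.23, adjusted p = 0.0212). The largest rise was of Ankrd1, a stress-responsive protein of muscle, from 0.944 ± 0.292 to 9.42 ± 1.10 FPKM (log2 fold change 2.43, SE 0.27, adjusted p = 0.013).

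At 12h, 7 of the 50 p53 target genes rose, 0 fell and 43 did not pass, and 19 were higher adjusted over the list alone. Gdf15, a stress-induced cytokine, had a log2 fold change of 1.80 and Eda2r, a death receptor family member, one of 1.10. The median of the list was 0.31 (adjusted p = 2.4e-17, and adjusted p = 0.413 with an estimated correlation). Of 44 G2/M and mitosis genes, 4 fell and 40 did not pass. Adjusted over the list alone, 40 were lower. Kif22, a chromosome-bound kinesin, fell by 1.18 on the log2 scale, and the list median was -0.77 (adjusted p = 6.35e-20, and adjusted p = 0.507 with an estimated correlation). Mki67, the proliferation marker Ki-67, was at 8.79 ± 2.88 against 17.6 ± 2.64 FPKM (adjusted p = 0.0649). Of 44 S phase and DNA replication genes, 1 fell and the median was -0.26 (adjusted p = 0.000876, and adjusted p = 0.641 with an estimated correlation).

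At 12h 4 keratin-associated proteins of the hair rose. Of 15 hair shaft keratins 0 passed (median 0.27, adjusted p = 2.32e-05, and adjusted p = 0.511 with an estimated correlation). Of 53 keratin-associated proteins, 4 rose, 0 fell and 49 did not pass, and 28 were higher adjusted over the list alone (median 0.49, adjusted p = 2.08e-29, and adjusted p = 0.413 with an estimated correlation). Krtap4-6 rose from 340.2 ± 5.51 to 768 ± 89.7 FPKM and Krtap4-13 from 46.8 ± 15.3 to 109 ± 9.14 FPKM. Of 16 inner root sheath genes, which form the tube that moulds the shaft, 1 rose (Padi1, a peptidylarginine deiminase, by 0.61 on the log2 scale), with a list median of 0.36 (adjusted p = 6.22e-08, and adjusted p = 0.507 with an estimated correlation). Cxcl10, a chemokine induced by interferon, rose from 3.15 ± 1.63 to 18.9 ± 7.81 FPKM and Serpina3n, a secreted protease inhibitor, from 19.3 ± 6.55 to 105 ± 58.3 FPKM. Of 18 circadian clock genes, 3 fell, which were Dbp, Nr1d1 and Nr1d2, all controlled by the clock, though the call of Dbp ended after median-of-ratios scaling and quantile normalization and that of Nr1d2 with hair genes left out. Nr1d1 fell from 15.6 ± 2.45 to 6.49 ± 1.09 FPKM, while the list median was 0.05 (adjusted p = 0.383). The clock list had a median of 0.35 at 6h (adjusted p = 0.00315, and adjusted p = 0.507 with an estimated correlation). At 24h its median was -0.115 (adjusted p = 0.857). Time of day was not tested and cannot be told apart from time since injection for these genes. Of 24 skeletal muscle genes 8 fell, and of 20 adipocyte genes 1 fell, Adrb3, the beta-3 adrenergic receptor (median -0.61, adjusted p = 8.19e-05, and adjusted p = 0.565 with an estimated correlation). Of 24 dermal fibroblast and matrix genes 0 passed at 12h (median -0.32, adjusted p = 0.0452, and adjusted p = 0.708 with an estimated correlation).

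The 147 calls at 12h were 38 higher and 109 lower genes as deposited, 40 and 45 after median-of-ratios scaling, 45 and 58 after quantile normalization, and 41 and 61 with hair genes left out. The count fell to 4 with no filter on low values, to 0 without 0h library 2, 21 without 0h library 3 (13 higher and 8 lower), 39 without 12h library 2, 46 without 12h library 3 and 91 without 48h library 2, and rose to 243 without either 6h library. All 147 kept their sign with each library left out, and 0 of the 43 named genes past the threshold passed with each library left out. The counts for p53 targets, G2/M genes, keratin-associated proteins, skeletal muscle and clock genes were each 0 without 0h library 2.

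**Figure D2:**
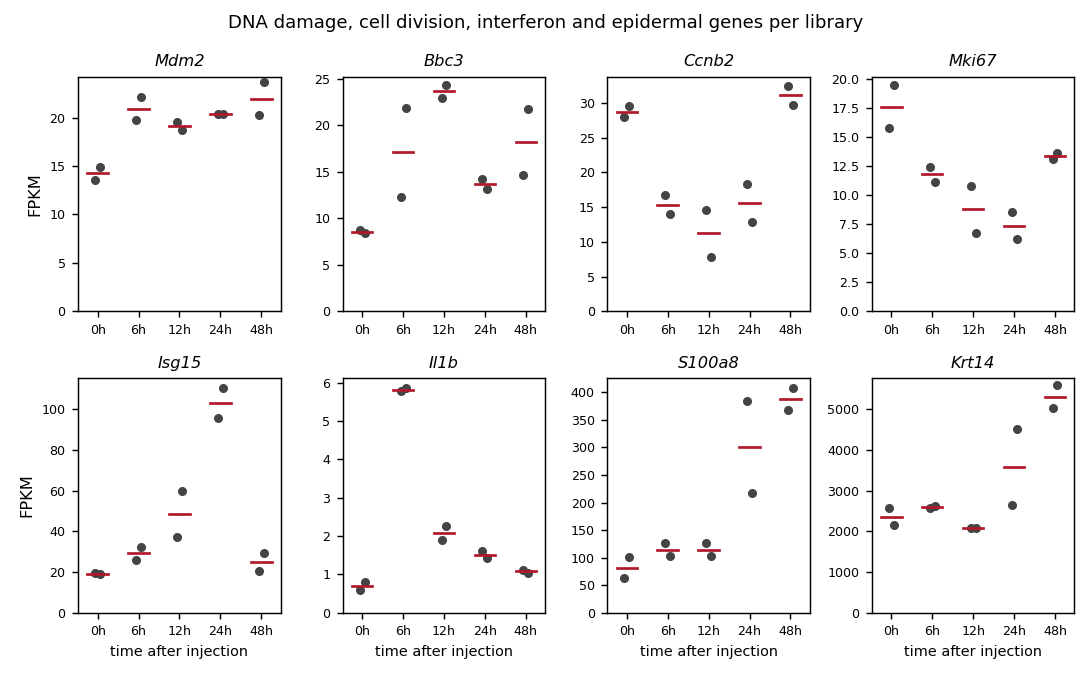
FPKM of 8 genes in each library (points, 2 per time) with the mean of each time (lines), against time after injection. Mdm2 and Bbc3 are p53 targets, Ccnb2 and Mki67 genes of dividing cells, Isg15 an interferon-stimulated gene, Il1b a cytokine, S100a8 an alarmin of stressed epidermis and neutrophils, and Krt14 a keratin of basal epidermis. Il1b is highest at 6h (5.81 FPKM), Isg15 at 24h (103 FPKM) and Krt14 at 48h (5304 FPKM).

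At 24h 12 of 30 interferon response genes had risen. Isg15, an interferon-stimulated ubiquitin-like protein, rose from 19.2 ± 0.516 to 103 ± 10.6 FPKM (log2 fold change 2.37, SE 0.23, adjusted p = 0.00189). Serpina3n reached 195.5 ± 23.4 FPKM (log2 fold change 3.31, SE 0.40, adjusted p = 0.00501), and Lcn2, which encodes the iron-sequestering protein lipocalin 2, rose from 3.45 ± 0.179 to 45.9 ± 18.6 FPKM (log2 fold change 3.34, SE 0.61, adjusted p = 0.0228). Saa3 and Saa2, serum amyloid proteins, and Cxcl13, a chemokine that attracts B cells, were also among the 10 largest rises, with log2 fold changes of 3.70, 3.44 and 3.46, although Saa3 did not pass after quantile normalization. Saa3 was no lower at the earlier times, at 131 ± 128 FPKM at 6h and 124 ± 116 at 12h against 71.2 ± 37.7 at 24h, but with libraries too far apart to pass (adjusted p = 0.103 and 0.0502). Saa2 was at 12.8 ± 4.55 FPKM at 6h (adjusted p = 0.127) against 13.8 ± 7.09 at 24h. Of the interferon genes 0 fell and 18 did not pass, and 26 were higher adjusted over the list alone. The list median was 1.02 (adjusted p = 9.07e-28, and adjusted p = 0.413 with an estimated correlation). Ifit3, an antiviral protein, rose from 3.56 ± 0.338 to 16.9 ± 2.50 FPKM and Oasl2 from 1.73 ± 0.479 to 10.2 ± 2.52 FPKM.

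Of 24 genes of stressed epidermis, which keratinocytes make after barrier damage, 7 rose at 24h, 0 fell and 17 did not pass, and 14 were higher adjusted over the list alone (median 1.04, adjusted p = 8.84e-13, and adjusted p = 0.417 with an estimated correlation). S100a8 rose from 81.7 ± 27.9 to 301 ± 118 FPKM and Slpi, an antimicrobial protease inhibitor, from 3.50 ± 0.686 to 20.9 ± 8.79 FPKM. The list of neutrophil and mast cell genes had 3 rises, S100a8, S100a9 and Lcn2, which stressed keratinocytes also make, while its other 12 genes did not pass (median 0.27, adjusted p = 0.0017, and adjusted p = 0.511 with an estimated correlation). Of 23 macrophage and dendritic cell genes and 9 lymphocyte genes 0 passed at 24h, with medians of 0.15 (adjusted p = 0.159) and -0.35 (adjusted p = 0.12). Only 9 of the 30 listed lymphocyte genes were tested, so these values say little about lymphocytes. Of 50 p53 target genes 9 rose at 24h and 16 were higher adjusted over the list alone. Eda2r rose from 0.898 ± 0.226 to 4.83 ± 1.09 FPKM, and the median was 0.36 (adjusted p = 7.44e-16, and adjusted p = 0.413 with an estimated correlation).

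Single signals of the hair matrix fell at 24h, among them Lef1 and Shh, while Wnt10b did not pass (adjusted p = 0.0705). Lef1, the transcription factor of Wnt signalling in the hair precortex (chromosome 3, 131110471 to 131224356), fell from 22.9 ± 0.90 to 10.8 ± 1.92 FPKM (log2 fold change -1.03, SE 0.16, adjusted p = 0.0115). Shh, the Sonic hedgehog ligand made on 1 side of the matrix (chromosome 5, 28456815 to 28467256), fell from 6.21 ± 1.22 to 1.69 ± 0.0870 FPKM (log2 fold change -1.41, SE 0.23, adjusted p = 0.0158). Of 12 Hedgehog pathway genes 3 fell, among them Shh and Ptch1, a Hedgehog receptor that did not pass with hair genes left out, with a list median of -0.49 (adjusted p = 0.000722, and adjusted p = 0.507 with an estimated correlation). Of 15 hair matrix and precortex regulators 3 fell (median -0.35, adjusted p = 0.0123, and adjusted p = 0.641 with an estimated correlation), and of 31 Wnt pathway genes 3 fell (median -0.20, adjusted p = 0.0562). Lef1 is in both the matrix and the Wnt list and Shh in both the matrix and the Hedgehog list. These lists are therefore not separate at any time. Of 44 G2/M genes 5 fell and 33 were lower adjusted over the list alone (median -0.68, adjusted p = 3.05e-12, and adjusted p = 0.511 with an estimated correlation), and Mki67 fell to 7.39 ± 1.68 FPKM (log2 fold change -1.16, SE 0.21, adjusted p = 0.0228). Of 53 keratin-associated proteins 11 rose, 0 fell and 42 did not pass, and 34 were higher adjusted over the list alone, with a median of 0.58 (adjusted p = 2.49e-26, and adjusted p = 0.413 with an estimated correlation).

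The 452 calls at 24h were 187 higher and 265 lower genes as deposited, but 304 and 161 after median-of-ratios scaling, 272 and 190 after quantile normalization, and 230 and 161 with hair genes left out. The count was 179 with no filter, 244 in a fit of the 2 times alone, 34 without 0h library 2 (18 higher and 16 lower), 100 without 0h library 3 (57 and 43), 230 without 24h library 2 (118 and 112) and 79 without 24h library 3. All 452 kept their sign, and 11 of the 63 named genes past the threshold passed with each library left out, among them Isg15, Ankrd1, Myog, Eda2r, Dcxr and Krtap4-13. Without 0h library 2 the interferon count was 1, the p53 target count 3, the keratin-associated protein count 1, and the counts for stressed epidermis, neutrophil and mast cell, G2/M, Hedgehog, hair matrix, Wnt and skeletal muscle genes each 0. Krt35, a keratin of the early hair cortex, fell from 960 ± 24.9 to 594 ± 113 FPKM (adjusted p = 0.0318), a call that ended after median-of-ratios scaling.

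**Figure D3:**
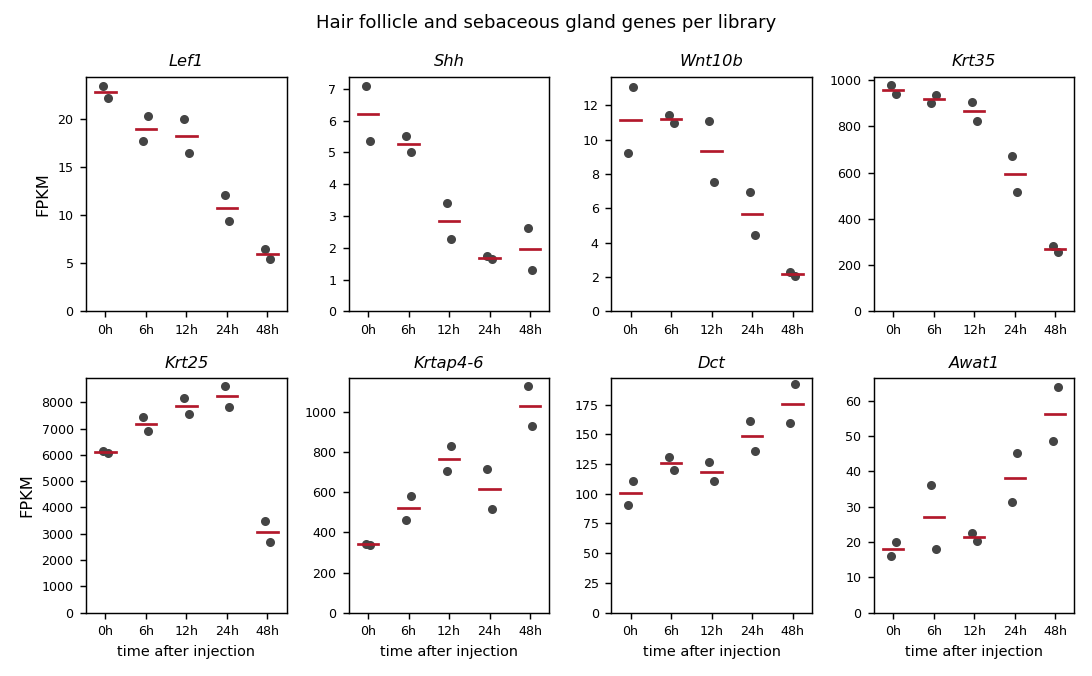
FPKM of 8 hair follicle and sebaceous gland genes in each library (points, 2 per time) with the mean of each time (lines), against time after injection. Lef1, Shh and Wnt10b are regulators of the hair matrix, Krt35 a hair cortex keratin, Krt25 an inner root sheath keratin, Krtap4-6 a keratin-associated protein, Dct a pigment enzyme and Awat1 an enzyme of sebum wax esters. Lef1 falls from 22.9 FPKM at 0h to 5.98 at 48h, while Krtap4-6 rises from 340.2 to 1029 FPKM.

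The hair matrix regulators as a list were furthest below 0h at 48h. Wnt10b, a Wnt ligand of the growing follicle, fell from 11.2 ± 2.74 to 2.19 ± 0.157 FPKM (log2 fold change -1.91, SE 0.23, adjusted p = 0.00124), and Lef1 fell to 5.98 ± 0.696 FPKM (log2 fold change -1.78, SE 0.16, adjusted p = 0.000323). Of 15 hair matrix and precortex regulators 11 fell, 0 rose and 4 did not pass, and 11 were lower adjusted over the list alone (median -0.93, adjusted p = 3.92e-07, and adjusted p = 0.507 with an estimated correlation). Msx1, a homeobox regulator, fell by 2.04 and Trps1, a GATA-type repressor, by 1.18 on the log2 scale. Of 31 Wnt pathway genes 10 fell and 3 rose, among the rises Wnt16 from 0.742 ± 0.394 to 4.74 ± 1.06 FPKM (median -0.26, adjusted p = 0.00623, and adjusted p = 0.561 with an estimated correlation). Of 12 Hedgehog pathway genes 5 fell and 1 rose (median -0.55, adjusted p = 0.00782, and adjusted p = 0.536 with an estimated correlation), and Gli1, the transcription factor that reports Hedgehog activity, fell from 30.9 ± 6.74 to 13.6 ± 1.69 FPKM. Among 24 ligands and targets of BMP, TGF-beta and Notch signalling 5 fell, among them Id3 and Smad6 by 0.88 and 0.98 on the log2 scale (median -0.16, adjusted p = 0.15).

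At 48h 8 of 16 inner root sheath genes and the early cortex keratin Krt35 were lower than at 0h, while 21 of 53 keratin-associated proteins were higher. Krt35 (chromosome 11, 100092193 to 100096241) fell from 960 ± 24.9 to 270.1 ± 16.7 FPKM (log2 fold change -1.83, SE 0.14, adjusted p = 0.000236). Of the inner root sheath genes 1 rose and 7 did not pass, and among the falls were Krt74 from 21.6 ± 0.646 to 3.12 ± 1.06 FPKM and Krt25, from 6123 ± 53.9 to 3079 ± 565 FPKM (list median -0.57, adjusted p = 0.000109, and adjusted p = 0.511 with an estimated correlation). The GENCODE M21 annotation lists Krt74 as a transcribed pseudogene in the mouse. Of 15 hair shaft keratins 2 rose and 3 fell, with Krt34 from 1325 ± 45.0 to 2087 ± 42.2 FPKM (median -0.09, adjusted p = 0.33). Of 53 keratin-associated proteins 21 rose, 0 fell and 32 did not pass, and 30 were higher adjusted over the list alone (median 0.56, adjusted p = 9.14e-15, and adjusted p = 0.507 with an estimated correlation). Krtap4-6 reached 1029 ± 141 FPKM and Krtap2-4 rose from 550.2 ± 3.49 to 1473 ± 186 FPKM. Of 19 melanocyte genes 2 rose, Dct from 100.5 ± 14.1 to 175.8 ± 23.0 FPKM and Pmel from 105.7 ± 2.58 to 189.5 ± 16.7 FPKM (median 0.14, adjusted p = 0.0583). The melanocyte list had passed earlier, with medians of 0.21 at 12h and 0.30 at 24h (adjusted p = 0.000713 and 5.25e-07, and adjusted p = 0.511 and 0.507 with an estimated correlation). Of 19 outer root sheath and bulge genes 1 rose, Sox9, and 2 fell, Aldh1a3 and, except with hair genes left out, Fgf5 (median 0.22, adjusted p = 0.422). Of 19 dermal papilla genes 2 fell, the secreted Wnt inhibitors Wif1 and Notum, the latter not past under any of the 3 other scalings (median -0.19, adjusted p = 0.398). Wif1 and Notum are also in the Wnt list.

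The p53 target genes were furthest from 0h at 48h. Of 50 tested, 25 rose, 0 fell and 25 did not pass, and 33 were higher adjusted over the list alone (median 0.57, adjusted p = 2.48e-15, and adjusted p = 0.413 with an estimated correlation). This was the 1 list past the threshold with fry (adjusted p = 0.027). Mgmt, which removes alkyl groups from guanine in DNA, rose from 6.75 ± 2.50 to 38.6 ± 7.46 FPKM (log2 fold change 2.38, SE 0.25, adjusted p = 0.000709). Mdm2 rose to 22.0 ± 2.42 FPKM (log2 fold change 0.59, SE 0.12, adjusted p = 0.0169) and Bax, a pore-forming effector of apoptosis, from 164 ± 16.1 to 230.2 ± 23.7 FPKM (adjusted p = 0.0376, but not past the threshold after median-of-ratios scaling). Cdkn1a was at 241 ± 12.3 FPKM (adjusted p = 0.112) and Trp53, the gene of p53 itself, at 36.6 ± 2.74 against 36.3 ± 2.44 FPKM at 0h (adjusted p = 0.976). Of 28 apoptosis regulators 8 rose and 1 fell, with Pmaip1, which encodes NOXA, from 2.76 ± 1.27 to 10.03 ± 1.51 FPKM (median 0.27, adjusted p = 0.00341, and adjusted p = 0.507 with an estimated correlation). Of the 30 listed apoptosis regulators 6 are also in another list. Bax and Pmaip1 are also p53 targets, so these 2 lists are not separate. Of 44 G2/M genes 0 passed at 48h (median 0.09, adjusted p = 0.226). Of 44 S phase genes 2 rose, Chaf1b and Cdc45, and 1 fell, E2f2 (median 0.31, adjusted p = 1e-05, and adjusted p = 0.536 with an estimated correlation). Of 32 genes of DNA crosslink and homologous repair 1 rose, Fanci (median 0.16, adjusted p = 0.0575).

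At 48h 11 of 20 sebaceous gland genes and 5 of 27 interfollicular epidermis genes rose. Krt14 and Krt5, the keratins of basal keratinocytes, rose from 2359 ± 283 to 5304 ± 392 FPKM (log2 fold change 1.17, SE 0.22, adjusted p = 0.0113) and from 1521 ± 145 to 3013 ± 168 FPKM (log2 fold change 0.99, SE 0.17, adjusted p = 0.00732). Krt2, a keratin of the upper epidermis, rose from 4.70 ± 0.924 to 84.4 ± 47.5 FPKM (log2 fold change 3.79, SE 0.43, adjusted p = 0.00101). Of 27 interfollicular epidermis genes 5 rose, 1 fell and 21 did not pass (median 0.48, adjusted p = 7.46e-05, and adjusted p = 0.511 with an estimated correlation). Of 24 stressed epidermis genes 8 rose, with S100a8 at 388 ± 28.4 FPKM (median 1.10, adjusted p = 4.42e-06, and adjusted p = 0.507 with an estimated correlation). Of 20 sebaceous gland genes 11 rose, 0 fell and 9 did not pass, and 12 were higher adjusted over the list alone (median 0.84, adjusted p = 1.72e-06, and adjusted p = 0.507 with an estimated correlation). Awat1 rose from 18.0 ± 2.64 to 56.3 ± 10.9 FPKM and Scd3, a fatty acid desaturase, from 19.0 ± 1.77 to 53.5 ± 5.90 FPKM. Atp12a, a proton pump of epithelia, rose from 6.15 ± 3.56 to 44.1 ± 13.4 FPKM. Spink4, a secreted protease inhibitor family member, was at 16.5 ± 0.477 FPKM at 48h and listed at 0 in both 0h libraries.

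Of 15 neutrophil and mast cell genes 3 rose at 48h, Lcn2, S100a8 and Hdc (median 0.51, adjusted p = 0.00812, and adjusted p = 0.561 with an estimated correlation), and of 23 macrophage and dendritic cell genes and 9 lymphocyte genes 0 passed (medians -0.12 and 0.28, adjusted p = 0.165 and 0.122). Of 22 inflammatory cytokines and chemokines 4 rose (median 0.31, adjusted p = 0.00733, and adjusted p = 0.523 with an estimated correlation), among them the monocyte chemokines Ccl7, from 2.93 ± 0.596 to 21.8 ± 8.84 FPKM, and Ccl2, from 2.02 ± 1.32 to 10.8 ± 3.46 FPKM. Of 30 interferon response genes 2 rose, among them Irf9 (median 0.25, adjusted p = 0.00955, and adjusted p = 0.704 with an estimated correlation). Of 18 endothelial genes 2 rose, Cldn5 and Pecam1 (median 0.33, adjusted p = 0.0152, and adjusted p = 0.644 with an estimated correlation). Defb8, a beta-defensin, fell from 165 ± 82.5 to 1.51 ± 2.14 FPKM (log2 fold change -6.28, SE 0.73, adjusted p = 0.00113), and Retnla, a secreted protein of fat and activated macrophages, from 98.5 ± 25.2 to 12.4 ± 1.06 FPKM. Selenbp1, a methanethiol oxidase, fell from 156.5 ± 7.49 to 15.6 ± 0.363 FPKM (log2 fold change -3.24, SE 0.13, adjusted p = 4.1e-06). Of 18 clock genes 3 rose, among them Bhlhe41 and Tef, and 1 fell, Nfil3 (median 0.32, adjusted p = 0.00315, and adjusted p = 0.507 with an estimated correlation), while Per2 was at 1.79 ± 0.479 against 1.29 ± 0.159 FPKM (adjusted p = 0.487). Of 20 adipocyte genes 1 rose, Dgat2, and 2 fell, Pck1 and Slc2a4 (median -0.14, adjusted p = 0.345), and Adipoq, the adiponectin gene, was at 75.9 ± 42.7 against 87.6 ± 31.7 FPKM (adjusted p = 0.73). Of 24 dermal fibroblast and matrix genes 1 rose, Crabp1, and 2 fell, Mfap5 and Dpp4 (median 0.16, adjusted p = 0.476).

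The other stress lists held few calls at 48h. Of 20 glucocorticoid-responsive genes 1 rose, Lcn2 (median 0.07, adjusted p = 0.356). Of 24 NRF2 and oxidative stress genes 1 rose, the glutathione peroxidase Gpx2, and 1 fell, G6pdx, which did not pass with hair genes left out (median 0.27, adjusted p = 0.122). Of 24 genes of ATF4 and the unfolded protein response 2 rose, Nupr1 and Chac1 (median 0.21, adjusted p = 0.0607), and of 24 immediate-early genes 2 rose, Cyr61 and Btg2 (median -0.07, adjusted p = 0.972). Nupr1, a stress-induced chromatin protein, rose from 161 ± 8.30 to 303 ± 0.654 FPKM. Earlier, some of these lists passed with the preset correlation, but none with an estimated correlation. Glucocorticoid-responsive genes had medians of 0.39 at 6h, 0.39 at 12h and 0.235 at 24h (adjusted p = 0.000224, 1.97e-06 and 0.00341). NRF2 genes were at 0.25, 0.185 and 0.11 (adjusted p = 0.00346, 0.000289 and 0.00212), and immediate-early genes at 0.26 at 6h and 0.21 at 12h (adjusted p = 0.00447 and 1.38e-05).

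Skeletal muscle genes, from the thin muscle sheet included in full-thickness skin, had a list median below 0 at every time, and genes of muscle moved in 2 directions by 48h. Of 24 genes 12 fell at 24h (median -0.89, adjusted p = 3.49e-10, and adjusted p = 0.507 with an estimated correlation) and 16 fell at 48h, when 8 did not pass and 21 were lower adjusted over the list alone (median -1.22, adjusted p = 1.15e-15, and adjusted p = 0.417 with an estimated correlation). Myh4 and Myh2, myosins of fast fibres, fell from 419 ± 1.28 to 45.7 ± 25.2 FPKM (log2 fold change -3.28, SE 0.53, adjusted p = 0.00561) and from 28.8 ± 16.8 to 2.2 ± 0.367 FPKM (log2 fold change -3.10, SE 0.42, adjusted p = 0.00237). Casq1 fell to 38.1 ± 2.25 FPKM and Actc1, the cardiac form of alpha-actin, from 24.3 ± 4.0 to 0.641 ± 0.771 FPKM. The largest rises at 48h included 3 other genes of muscle. Ankrd1 rose from 0.944 ± 0.292 to 71.3 ± 9.37 FPKM (log2 fold change 5.22, SE 0.27, adjusted p = 1.39e-05), Myog, the transcription factor myogenin, from 0.866 ± 0.00198 to 25.2 ± 6.02 FPKM (log2 fold change 3.80, SE 0.19, adjusted p = 1.39e-05) and Ankrd2 from 14.3 ± 3.18 to 123 ± 56.1 FPKM (log2 fold change 2.96, SE 0.45, adjusted p = 0.00439).

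**Figure D4:**
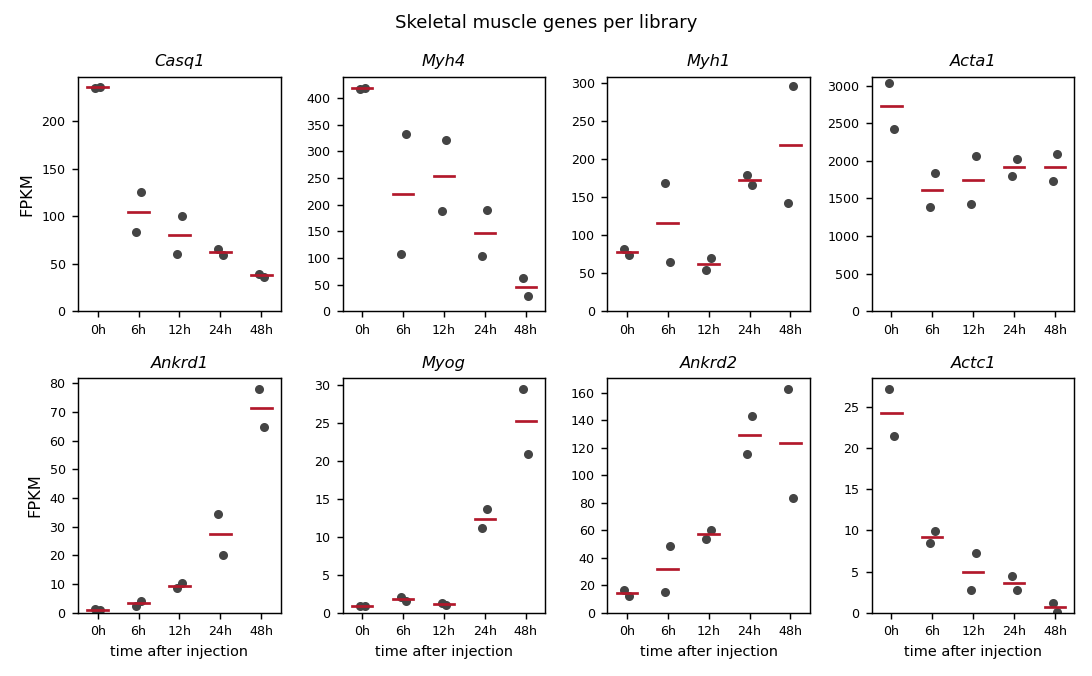
FPKM of 8 skeletal muscle genes in each library (points, 2 per time) with the mean of each time (lines), against time after injection. Casq1, Myh4, Myh1, Acta1 and Actc1 encode parts of the contractile apparatus or calcium store, Ankrd1 and Ankrd2 stress-responsive muscle proteins and Myog a muscle transcription factor. Myh1 and Acta1 fell outside the rule for named genes. Myh4 falls from 419 FPKM at 0h to 45.7 at 48h, while Myog rises from 0.866 to 25.2 FPKM.

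The 1215 calls at 48h were 654 higher and 561 lower genes as deposited, and 885 and 418 with hair genes left out. The count was 418 without 0h library 2 (193 higher and 225 lower), 457 without 0h library 3, 558 without 48h library 2 and 339 without 48h library 3 (152 and 187). All 1215 kept their sign with each library left out, and 41 of the 106 named genes past the threshold passed each time, among them Lef1, Wnt10b, Krt35, Krt74, Krt2, S100a8, Mgmt, Ankrd1, Myog, Myh2 and Casq1. The lowest count over the libraries left out was 9 for p53 targets and 3 for hair matrix regulators, inner root sheath genes and stressed epidermis (each without 48h library 3), 8 for keratin-associated proteins, 3 for sebaceous genes and 11 for skeletal muscle (each without 0h library 2), 4 of the Wnt falls and 1 of the epidermal rises (each without 0h library 3), 1 of the Hedgehog falls (without 48h library 3), and 1 of the apoptosis rises and 0 of the cytokine rises (each without 0h library 2). Without 0h library 2 the counts were also 0 for the falls of BMP, TGF-beta and Notch genes and of dermal papilla genes and for the rises of hair shaft keratins, endothelial and interferon response genes, and 1 for the rises of neutrophil and mast cell genes. Without 48h library 3 they were 0 for the rises of melanocyte, Wnt and clock genes. Without 0h library 3 they were 0 for the falls of adipocyte and of dermal fibroblast and matrix genes.

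Comparisons between later times set no 0h mean against another, but the 0h libraries enter the spread of the fit. Between 6h and 12h 0 genes passed (limma), with 1556 at an unadjusted p under 0.05, and 8 passed without 6h library 3, 2 with no filter, 2 without trend and 1 in a fit of the 2 times alone. Between 12h and 24h 3 genes rose: Myog from 1.11 ± 0.235 to 12.4 ± 1.83 FPKM (log2 fold change 2.66, SE 0.19, adjusted p = 0.001), Tcf15 (1.55, SE 0.18, adjusted p = 0.0337) and the phosphatase Dusp13 (1.26, SE 0.12, adjusted p = 0.00687). Between 24h and 48h 166 genes rose and 142 fell. Krt2 rose from 4.11 ± 1.51 to 84.4 ± 47.5 FPKM and Krt74 fell from 21.4 ± 1.76 to 3.12 ± 1.06 FPKM (adjusted p = 0.00645 and 0.000529). The split was 85 higher and 196 lower after median-of-ratios scaling and 113 and 220 after quantile normalization. The count of 308 was 112 with no filter, 0 in a fit of the 2 times alone, 189 without 0h library 2 (91 higher and 98 lower), 190 without 0h library 3 (91 and 99), 30 without 24h library 2 (13 and 17), 191 without 24h library 3, 65 without 48h library 2 (18 and 47) and 18 without 48h library 3 (6 and 12). The 3 calls between 12h and 24h were 7 without either 6h library or 24h library 2, 1 without 12h library 2 or 24h library 3, 10 with a pseudocount of 0.1, 10 after median-of-ratios scaling, 8 with hair genes left out and 0 in a fit of the 2 times alone.

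Between 6h and 48h 370 genes rose and 413 fell. The largest rises were of Ankrd1 (log2 fold change 4.11, SE 0.27, adjusted p = 0.000138), Myog (3.25, SE 0.19, adjusted p = 7.59e-05) and Krt2 (3.24, SE 0.43, adjusted p = 0.00388), and the largest fall of Defb8 (-6.23, SE 0.73, adjusted p = 0.00271). The haemoglobin rows Hbb-b1,Hbb-bs and Hbb-b2 were the next largest falls, with spreads of 510 ± 333 and 103 ± 22.7 FPKM at 6h. The split was 470 and 329 with hair genes left out, 382 and 380 without 24h library 2 and 381 and 381 without 24h library 3. The count of 783 was 452 with no filter, 368 in a fit of the 2 times alone, 421 without 6h library 2, 379 without 6h library 3 (204 higher and 175 lower), 320 without 48h library 2 and 118 without 48h library 3. The count of 1002 at any time was 387 without 0h library 2, 451 without 0h library 3, 635 without 12h library 3, 359 without 48h library 2, 193 without 48h library 3 and 417 with no filter.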

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

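The explanations below were chosen after the patterns were seen, and their tests before the tested values were seen, except that of immune cell genes, whose values had been seen. Differences between the responses at later times were tested directly, as contrasts between those times in limma. Between 12h and 24h 3 genes differed, Myog (log2 fold change 2.66), Tcf15 (1.55) and Dusp13 (1.26). Between 24h and 48h 308 genes differed, with the largest rises in Krt2 (3.97), Spink4 (2.61) and Cma2 (1.90) and the largest falls in Kcnk16 (-2.71), Krt74 (-2.46) and Arg1 (-2.42). Between 6h and 48h 783 genes differed, with Ankrd1 (4.11), Myog (3.25) and Krt2 (3.24) highest and Defb8 (-6.23), Hbb-b1,Hbb-bs (-5.95) and Hbb-b2 (-5.35) lowest. Counts between 24h and 48h moved strongly with single libraries, from 308 to 18 without 48h library 3.

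Gene lists whose median moved between 24h and 48h were G2/M and mitosis (0.78), S phase and DNA replication (0.56), lymphocytes (0.56), circadian clock (0.50), sebaceous gland (0.49), interfollicular epidermis (0.39), DNA crosslink and homologous repair (0.26) and p53 target genes (0.22) upwards. Downwards moved red blood cells (-1.05), interferon response (-0.92), inner root sheath (-0.70), hair shaft keratins (-0.44), hair matrix and precortex regulators (-0.41), skeletal muscle (-0.33), macrophages and dendritic cells (-0.17) and melanocytes (-0.069). All of these passed with the preset correlation and none with an estimated correlation (smallest adjusted p = 0.431). The median of all genes moved by 0.086 between these times. Relative to it, p53 target genes moved by 0.131 and melanocyte genes by -0.155. Of 9 lymphocyte genes 1 rose, and of 19 melanocyte genes 1 fell. Of 44 G2/M genes 5 rose and 39 were higher adjusted over the list alone, and of 30 interferon genes 5 fell and 22 were lower adjusted over the list alone.

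Skeletal muscle genes had a median log2 fold change of -1.22 (SD 0.99 over 24 genes) at 48h, where 16 fell (adjusted p = 0.417 with an estimated correlation). A smaller share of muscle in the later samples would by itself lower all genes of muscle alike. Other muscle genes (receptor, atrophy and myogenic genes, 10 of them tested) were listed once Myog and Chrna1 had been seen to rise but before their own values were looked at, and 8 rose, 0 fell, and their median was 1.22, 2.44 above the list (permutation p = 0.00011, two-sided, 100000 resamples over genes), while the 5 with a mean of at least 5 FPKM had a median of 0.84. The permutation treats genes as independent, which genes of 1 tissue need not be, so its p may be too small. Hair shaft keratins and keratin-associated proteins held 12.4% of the summed FPKM at 0h and 16.7% at 48h. Dilution by this rise could account for little of the fall. Leaving these genes out and rescaling the rest, an outcome set by these shares, moved the median to -1.15. The rise of the other muscle genes argues against a smaller share of muscle as the only change among genes of muscle. It cannot tell whether a smaller share caused the whole fall of the list, since both could occur together. No biological explanation was tested, and time since depilation is left open.

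Interferon response genes had a median of 1.02 at 24h, where 12 of 30 rose. A gain of macrophages, dendritic cells and lymphocytes together at 24h is argued against by their pooled genes, whose median was -0.085 (32 genes). The SD over these genes divided by the root of their number was 0.08. This error treats genes as independent, which genes of 1 cell type need not be, and does not measure the spread between libraries. The pool cannot tell a gain of 1 of these cell types from a loss of another. Taken apart, macrophage and dendritic cell genes (23 tested) had a median of 0.15 and lymphocyte genes (9 tested of 30 listed) one of -0.35. The pool therefore says little about lymphocytes. Neutrophil and mast cell genes, which were not in the pool, had a median of 0.27. A single 24h library is argued against by the list test without each 24h library, where the interferon median was 1.12 without library 2 and 0.92 without library 3 and the larger adjusted p was 9.21e-25 with the preset correlation (adjusted p = 0.413 with an estimated correlation over all libraries). No biological explanation was tested, and other immune cells and time since depilation are left open.

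Keratin-associated proteins had medians above 0 at 12h, 24h and 48h, and 0.58 at 24h (adjusted p = 0.413 with an estimated correlation). A preference for short transcripts is argued against by 1929 other well-expressed genes of up to 1157 bases, with a median of -0.13, and a GC effect by 2854 other well-expressed genes of 48.1% to 55.9% GC, with a median of -0.10. Reads shared between copies of a named subfamily are argued against by the 14 proteins alone in their listed subfamily, whose median was 0.40 against 0.61 for the other 39. Of the 14, Krtap20-2 (-0.774), Krtap24-1 (-0.05) and Krtap21-1 (0.003) did not rise, and the rest lay at 0.184 or above. Subfamilies were read from gene symbols and not from sequences, so the 14 may still share reads with other genes. No biological explanation was tested, and time since depilation is left open.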

How the results depend on the processing

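Of 2670 tests of named genes with 1 library left out, 2045 stayed on their side of the threshold in the same direction, 623 lost and 2 gained significance, and 0 reversed, and of 2336 under other settings 2074, 256, 6 and 0. For lists these were 1224, 39, 56 and 1 of 1320, and 1118, 158, 32 and 0 of 1308. The 1 reversal was interfollicular epidermis at 12h without 12h library 3 (median -0.14, against 0.21 without 12h library 2). Over the libraries left out, counts ranged from 1 to 14 at 6h, 0 to 243 at 12h, 34 to 596 at 24h, 339 to 1400 at 48h, 0 to 8 for 12h against 6h, 1 to 7 for 24h against 12h, 18 to 352 for 48h against 24h, 118 to 762 for 48h against 6h, 193 to 1051 at any time, and 68 to 79 for lists. A time left with 1 library was assumed to vary like the others, and fewer libraries lower the power of the test. The lack of reversals among named genes says little, since those past the threshold were picked for differing in these same libraries. A pseudocount of 0.1 gave 10 genes for 24h against 12h. No filter on low values gave 3 at 6h, 4 at 12h, 179 at 24h, 2 for 12h against 6h, 112 for 48h against 24h, 452 for 48h against 6h and 417 at any time, and a mean of at least 5 FPKM gave 2 at 6h. Median-of-ratios scaling gave 85 at 12h and 10 for 24h against 12h, and leaving out hair genes gave 8 for the latter. Limma without trend gave 2 for 12h against 6h. A fit of only the 2 times gave 35 at 6h, 244 at 24h, 1 for 12h against 6h, 0 for 24h against 12h, 0 for 48h against 24h and 368 for 48h against 6h. Lists past the threshold numbered 0 with an estimated correlation and 1 with fry, which was chosen after seeing the data. The causes of these shifts were not tested. With the replicate number as a replicate block, counts were 99 at 6h, 322 at 12h, 5 for 12h against 6h, 42 for 24h against 12h and 507 for 48h against 24h, while correlations of the deviations of same-numbered libraries ran from -0.1 to 0.22 and 5 of 10 pairs exceeded 0.1. Since not every pair did, the numbers were not taken to pair the libraries, and a component shared by some of them is left open. Scalings moved the median of all genes by at most 0.09, and absolute depth, which limits low genes, is not known.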

Other observations

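Myh1, a fast-fibre myosin of the skeletal muscle list picked out after its values were seen, was at 219 ± 109 FPKM (SD, n = 2) at 48h against 77.9 ± 5.19 at 0h (log2 fold change 1.39, SE 0.41, adjusted p = 0.0657), while Myh4 and Myh2 fell. Among the receptor, atrophy and myogenic genes, whose own values had not been seen when they were listed, Chrnb1, a subunit of the acetylcholine receptor, rose from 4.19 to 8.33 FPKM (adjusted p = 0.00915), Myf6, a muscle transcription factor, from 7.91 to 21.5 FPKM (adjusted p = 0.0407) and Fbxo32, an atrophy ubiquitin ligase, from 6.34 to 10.9 FPKM (adjusted p = 0.02), while Trim63, the other atrophy ubiquitin ligase, did not pass (log2 fold change 0.77, SE 0.72, adjusted p = 0.554).

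Haemoglobin transcripts differed between libraries of a time. The row Hbb-b1,Hbb-bs was at 46.1 and 69.8 FPKM at 0h, 746 and 275 at 6h, 271 and 45.2 at 12h, 390 and 28.2 at 24h, and 32.8 and 0.598 at 48h.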
